A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

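Total RNA from mid-log cultures in rich medium was labelled with biotin and hybridised to Affymetrix yeast arrays, which carry probe sets for S. pombe and for Saccharomyces cerevisiae, per the labels' protocols. The labels name 3 groups with 2 arrays each: wild type, fkh2delta and fkh2-S2A. They give wild type and fkh2-S2A the same strain name and fkh2delta another, and they do not spell out the change in the S2A allele. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so p-values measure the spread between arrays, which may be technical.

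The deposited table holds one value per probe set and array on a log2 scale; the base was inferred from the range of the values. The arrays had nearly equal quantiles, so the authors' values were taken as already normalized between arrays and were used as deposited. The summary method, background correction and software are not given in the sources used here. Differences were not centred per gene. No pseudocount was needed on this scale, so no other pseudocount was tried.

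Of 10928 probe sets, 213 were controls and 5538 were listed in the platform annotation given for this work. Listed genes were matched to the S. pombe genes of assembly ASM294v3 by Entrez identifier, or by exact symbol (3 probe sets). The assembly was used for names, gene order and gene length, without coordinates. This gave 2936 S. pombe probe sets, of which 2917 had 1 gene and 19 had several, for 2899 genes; 110 symbols were updated. A further 2601 listed probe sets matched no S. pombe gene and 1 was mixed. The remaining 5177 probe sets are unnamed here and stayed out of the tests. The background level of an array was the 95th percentile of the 2601 listed probe sets without an S. pombe gene, and 2883 of the 2936 tested probe sets had a mean above it. A group with both arrays at or below that level gave a bound: the mean of the bright group against the mean of the dim group, with each dim array set to its background level where that was higher, written as "at least N-fold".

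Tests were made with limma 3.58.1 in R 4.3.3: 1 linear model over all 6 arrays with group as the sole term, moderated statistics (3 residual degrees of freedom, 5.73 prior degrees of freedom) and Benjamini-Hochberg adjustment over the 2936 probe sets of each of 3 comparisons, with a threshold of 0.05, two-sided. A second count asked for a change of at least 1 on the log2 scale (2-fold). On simulated data for fkh2delta against wild type over 2936 probe sets, the same steps recovered 87.0% of probe sets changed by 0.5 log2 and all of those changed by 1 or 2, with 4.78% false calls. The simulation changed 67, 67 and 66 probe sets by these sizes, in both directions, with independent noise and no trend between arrays. Many more probe sets were called in the data, so 4.78% is no error rate for them.

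Gene lists were fixed before the data were examined: M-phase genes, MBF targets, histones, septation, early meiosis, middle meiosis, mating, M-cell and P-cell genes, stress, ribosomal proteins, rRNA processing, respiration, iron uptake, flocculation, forkhead and MADS-box factors, the Cdk8 module, auxotrophic markers, phosphate uptake and S. cerevisiae marker genes. The 13 lists meant for a test and with at least 5 measured genes were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 13), and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. None of the 13 lists passed with an estimated correlation in any of the 3 comparisons; at an unadjusted p below 0.05 there were 0, 1 and 0 for fkh2delta, fkh2-S2A and the direct comparison. That form rests on 3 residual degrees of freedom, which leaves it little power, so not passing it says little about a list. Of the phosphate genes 1 probe set was measured, and since its annotation now points to an overlapping noncoding gene it is not named; it was 1.10 higher in fkh2delta, within error of wild type in fkh2-S2A (-0.02) and 1.13 lower in fkh2-S2A than in fkh2delta. The S. cerevisiae marker genes were not analysed here. A further list is among the 13 tested and is not reported here.

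Genes named in the report followed a rule set at the same time. Per comparison it takes the 12 highest rises and 12 deepest falls among probe sets with a single gene, an adjusted p below 0.05, groups that do not overlap, and at least 1 group above background on both arrays. It adds fkh2, sep1, mei4, fhl1 and mbx1, all M-phase and Cdk8 module genes, and the 4 members of each other list with the largest absolute change. The probe set with the highest mean over the 6 arrays stood for a gene; 14 genes had several.

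Alternatives were quantile normalization, median and trimmed-mean centring, 2 filters on dim probe sets, a test over all species, other eBayes priors (trend, robust), a fit on 2 groups, array weights, the replicate number as a block, each array left out in turn, other thresholds and other list tests. Added after seeing the data were a crossed replicate block, removal of each array's trend with gene length, unlisted probe sets above background, and leaving out ura4. Shared controls were simulated with 1000 draws from each probe set's residual spread. No 2 arrays held identical data; at most 2 probe sets had the same value on a pair of arrays.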

Results

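RNA from exponentially growing fission yeast (Schizosaccharomyces pombe) in rich medium was hybridised to an Affymetrix yeast expression array. The 6 arrays fell into 3 groups of 2: wild type, a strain lacking fkh2 (fkh2delta) and a strain carrying the fkh2-S2A allele. Fkh2 is a forkhead transcription factor known for its part in the periodic transcription of mitotic genes. The values were deposited on a log2 scale, and 2936 S. pombe probe sets were tested. Their median lay between 10.1 and 10.2 on each array, and the background level of the arrays lay between 5.17 and 5.35. With 2 arrays per group, the number of arrays limits the precision. Changes below are log2 differences between group means ± the standard error (SE) of the limma fit, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

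The deleted gene was read first, as a check of the labels. The fkh2 signal was 7.53 and 7.39 on the wild-type arrays, 4.34 and 4.05 on the fkh2delta arrays and 7.47 and 7.76 on the fkh2-S2A arrays. Both fkh2delta values lay below the background level, so that fkh2 was at least 4.86-fold lower than in wild type (adjusted p = 5.28e-07, n = 2 arrays per group, limma). In fkh2-S2A the fkh2 transcript differed from wild type by 0.16 ± 0.14, which did not pass the test (adjusted p = 0.407). The position of the fkh2 probes within the gene is not given in the sources used here. A marker gene of strain construction also separated the groups: ura4, which encodes an enzyme of uracil synthesis, fell by 6.89 ± 0.21 in fkh2delta (adjusted p = 1.01e-07) and was at the wild-type level within error in fkh2-S2A (0.16 ± 0.21, adjusted p = 0.604).

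**Figure D1:**
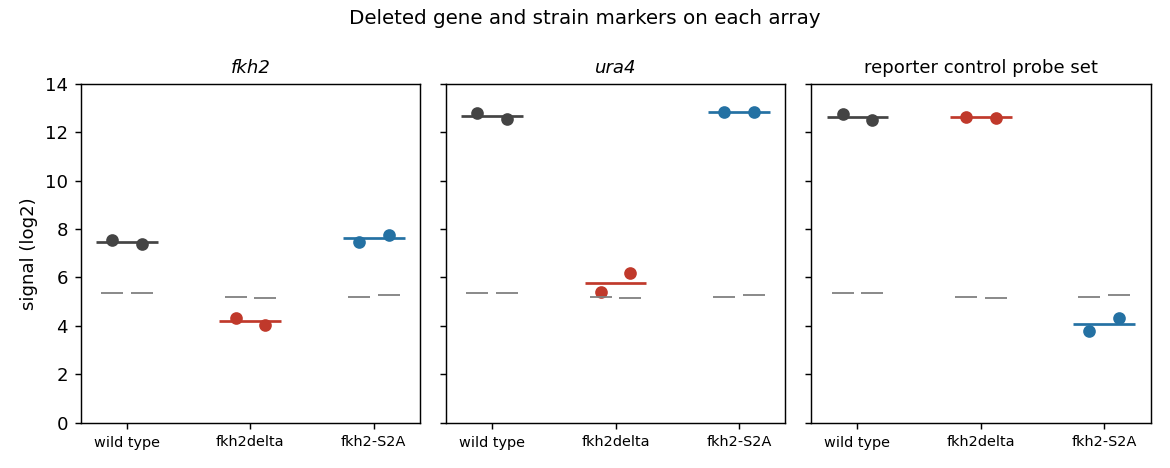
Signal (log2, vertical axis) of fkh2, ura4 and a reporter control probe set on each of the 6 arrays; points are arrays, coloured horizontal lines are group means and grey dashes are the background level of each array. The fkh2 signal is below background in fkh2delta, ura4 drops in fkh2delta alone, and the reporter probe set reads 12.6 on average in wild type and is below background in fkh2-S2A.

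The comparison of fkh2delta with wild type asked which transcripts differ in the strain lacking fkh2. The 2 groups also differ in strain name and in ura4, so an effect of fkh2 cannot be told apart from one of the strain. Genes transcribed in mitosis were higher in fkh2delta. Of 17 measured M-phase genes 15 rose (15 adjusted over the list alone) and the other 2, klp5 (0.24 ± 0.15) and cdc25 (-0.26 ± 0.14), did not pass. The highest rises were bir1 (1.62 ± 0.14), a chromosomal passenger protein gene, the type II myosin gene myp2 (1.55 ± 0.12), the contractile-ring gene cdc15 (1.22 ± 0.10), the kinesin gene klp6 (1.20 ± 0.10) and the Polo kinase gene plo1 (1.17 ± 0.12).

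The remaining M-phase genes that rose were ark1 (1.15 ± 0.13), chs2 (1.00 ± 0.12), imp2 (0.99 ± 0.11), fin1 (0.92 ± 0.11), slp1 (0.79 ± 0.10), spo12 (0.75 ± 0.11), klp8 (0.75 ± 0.10), pic1 (0.69 ± 0.12), mid1 (0.56 ± 0.11) and sid2 (0.33 ± 0.10, lost in 4 of 21 other settings). The median change of the M-phase list was 0.92, against a median of 0.16 over all probe sets. The camera test with a preset correlation called the list (adjusted p = 0.000946). The list did not pass with an estimated correlation (adjusted p = 0.521 with an estimated correlation), a form with little power here. It passed with fry (adjusted p = 0.00287).

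Many genes known for their transcription in meiosis were also higher in fkh2delta. Of 18 middle meiotic and sporulation genes 12 rose and 1 fell (12 and 1 adjusted over the list alone). The rises included the conserved meiotic gene meu14 (5.35 ± 0.09), the meiotic septin genes spn6 (at least 6.04-fold, since it was not above background in wild type) and spn7 (2.90 ± 0.17), and mcp4 (3.0 ± 0.11). With 5 genes at their bound and 1, not above background in either group, set to 0, the list's median was 0.85. Without these bounds it was 1.24 (camera adjusted p = 0.00545, adjusted p = 0.606 with an estimated correlation). Over 23 other settings this median ran from 0.57 to 1.37. Of 15 early meiotic genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), led by the recombinase gene dmc1 (3.08 ± 0.17) and the linear-element gene rec10 (2.24 ± 0.12). That list did not pass (camera adjusted p = 0.0677, adjusted p = 0.521 with an estimated correlation). Its median of 0.73 was 0.00080 with 4 genes at their bound and 5, not above background in either group, set to 0. The early meiotic list passed in 10 of 23 other settings, among them median centring (camera adjusted p = 0.0306), and not after quantile normalization (camera adjusted p = 0.844). Of 10 mating genes 4 rose and 2 fell (4 and 2 adjusted over the list alone). The rises were mei2 (2.19 ± 0.12), which encodes the RNA-binding regulator of meiotic entry, ste6 (1.95 ± 0.11), ste4 (1.14 ± 0.12) and fus1 (at least 1.96-fold). The mating list did not pass (camera adjusted p = 0.484). The mating-type-specific genes moved little: 1 of 7 M-cell genes rose (sxa2, 0.47 ± 0.13) and 1 fell (mam3, -0.65 ± 0.14), and of 3 P-cell genes map4 rose (0.48 ± 0.10) and map3 fell (-0.29 ± 0.11), with the same counts adjusted over the list alone. The map3 call was lost in 7 of 20 other settings, among them each fit that left out 1 array of the 2 groups, and the sxa2 call in 3 of 20.

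The highest single rise was in tlh2, a subtelomeric helicase gene, at least 46.2-fold above wild type, where it was not above background. Its family has near-identical copies and its 4 probe sets differed, with changes from 0.38 to 6.77, so the size for this gene is uncertain. Other high rises were meu6 (4.11 ± 0.14), mug103 (3.59 ± 0.15, above background on 1 of the 2 wild-type arrays), mug20 (3.56 ± 0.09), cid11 (3.51 ± 0.10), mug133 (at least 10.3-fold), crp79 (at least 5.16-fold), mug135 (3.20 ± 0.13), the measured gene next to the lost ura4 on 1 side, the proton pump gene pma2 (at least 5.13-fold) and the small heat-shock gene hsp16 (3.17 ± 0.13). After ura4 and fkh2, the deepest falls were wtf15 (-2.28 ± 0.16), the proline permease gene put4 (-2.12 ± 0.13), gut2 (-2.09 ± 0.19), the transcription factor gene klf1 (-2.08 ± 0.10), the amino acid transporter gene cat1 (-2.07 ± 0.13), rds1 (-2.05 ± 0.12), the catalase gene ctt1 (-2.05 ± 0.14) and sib2 (-2.02 ± 0.12), followed by psf2 (-1.85 ± 0.11) and seb1 (-1.72 ± 0.11).

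None of the following lists passed camera in fkh2delta, and most had genes that went both ways. Of 17 G1/S genes driven by MBF 7 rose and 4 fell, with the polymerase gene pol1 (2.04 ± 0.14) highest and cdt2 (-0.99 ± 0.12) lowest (camera adjusted p = 0.922). Of 14 septation genes 10 rose, such as the kinase gene sid1 (1.25 ± 0.20), and 2 fell, cdc16 (-1.33 ± 0.13) and mob1 (-0.32, chosen after its value was seen; camera adjusted p = 0.383). Of 13 stress genes 4 rose and 4 fell, with the metallothionein gene zym1 at 1.98 ± 0.10 against ctt1 (camera adjusted p = 0.882); camera's direction for this list was down while its median (0.06) and mean (0.28) were above 0. Of 9 iron uptake genes 4 rose, with the siderophore transporter gene str3 at 2.86 ± 0.30, and 2 fell (camera adjusted p = 0.882). Of 35 respiratory genes 8 rose and 11 fell, with cox5 lowest (-1.25 ± 0.10, camera adjusted p = 0.109). Of 20 rRNA processing genes 9 rose, with rrp6 at 1.32 ± 0.21, and 5 fell (camera adjusted p = 0.864). The counts of these 6 lists were the same adjusted over the list alone. Of 111 ribosomal protein genes 2 rose and 12 fell (1 and 2 adjusted over the list alone, 72 called with a mean-variance trend, camera adjusted p = 0.109), and of 9 histone genes 2 rose, hhf2 (0.33 ± 0.11) and hhf3 (0.25 ± 0.09), a count that was 0 adjusted over the list alone (limma; 3 of the 9 had an unadjusted p below 0.05 and 7 were called with a mean-variance trend; camera adjusted p = 0.509). The hhf2 and hhf3 calls were lost in 6 of 21 and 11 of 22 other settings.

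Lists too small or not meant for camera gave values alone. The 3 measured flocculation genes, pfl8 (-1.69 ± 0.15), cbf12 (-1.48 ± 0.12) and mbx2 (-0.64 ± 0.14), fell. Besides ura4, the auxotrophic marker genes ade6 (-1.38 ± 0.11), lys1 (-1.07 ± 0.11) and his3 (-0.79 ± 0.09) fell, and with leu1 5 of 7 passed. Among the forkhead and MADS-box genes sep1 (-0.79 ± 0.10) and mbx1 (-0.60 ± 0.15) fell, fhl1 (0.53 ± 0.09) rose, and mei4 (0.31 ± 0.13, adjusted p = 0.0673) did not pass. Of 4 measured genes of the Mediator Cdk8 module, med13 (0.53 ± 0.12) and srb11 (0.42 ± 0.10) passed, while srb8 (0.19 ± 0.11) and srb10 (0.16 ± 0.12) did not. Quantile normalization turned the direction of mei4 (-0.49), med13 (-0.21) and srb10 (-0.58).

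In all, 1879 of 2936 probe sets passed in fkh2delta, 1186 higher and 693 lower, and 379 of them changed at least 2-fold, 245 higher and 134 lower. The median of all probe sets was 0.16 higher in fkh2delta, a shift that was 0.033 after median centring, and the split became 979 higher and 908 lower, 1027 and 860 with trimmed-mean centring, or 965 and 893 after quantile normalization. The excess of 2-fold rises did not hold either: the 2-fold split was 176 higher and 195 lower after median centring, 189 and 183 with trimmed-mean centring, 123 and 196 after quantile normalization and 170 and 176 with the length trend removed. A measure of RNA quality moved with this group: the mean 3′ minus 5′ difference of 6 S. pombe control genes was 1.53 and 1.61 on the fkh2delta arrays against 1.27 and 1.27 in wild type and 1.35 and 1.24 in fkh2-S2A. The control genes differed, with changes in fkh2delta from -0.14 for GPD3 to 0.78 for SRB4. RNA quality and changes of single control transcripts were therefore not told apart.

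**Figure D2:**
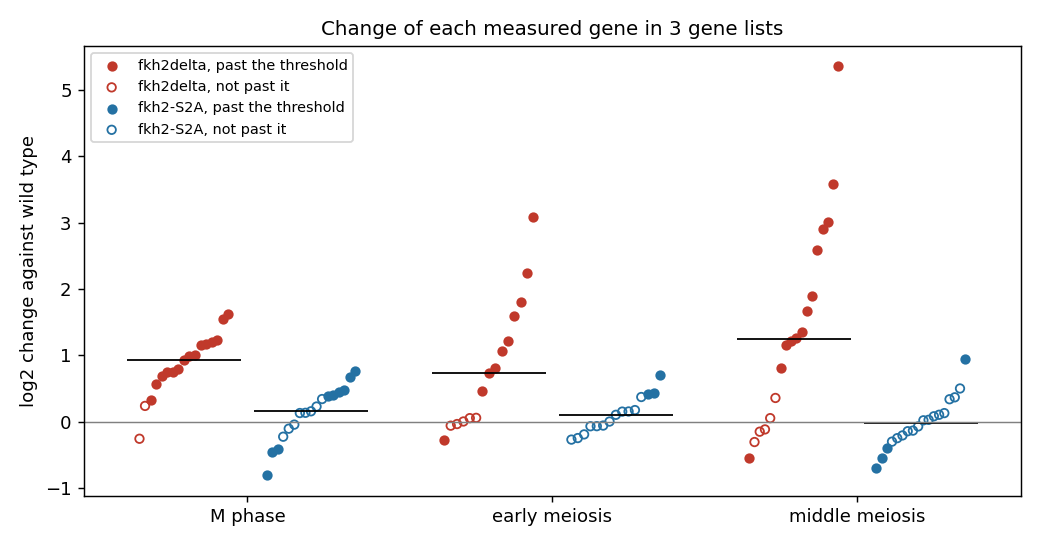
Log2 change against wild type (vertical axis) of each measured gene in 3 gene lists (horizontal axis), in fkh2delta (red) and fkh2-S2A (blue), n = 2 arrays per group; filled points passed the test, open points did not, and black lines are list medians. In fkh2delta the M-phase median is 0.92 and the middle meiotic median 1.24, while the same medians in fkh2-S2A are 0.15 and -0.03.

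The comparison of fkh2-S2A with wild type asked what the allele changes. An exchange of the wild-type and fkh2-S2A labels is left open in the closing section; it would turn every sign of this comparison, with 6 higher and 36 lower by 2-fold and aes1 the deepest fall, and the other 2 comparisons would change places with their signs turned. As labelled, the changes were smaller: 42 probe sets passed and changed at least 2-fold, 36 higher and 6 lower. The highest rise was aes1 (2.13 ± 0.09), followed by str3 (1.84 ± 0.30), the topoisomerase gene top2 (1.62 ± 0.12), spo15 (1.47 ± 0.15), lon1 (1.31 ± 0.13), the myosin gene myo52 (1.30 ± 0.14), alm1 (1.30 ± 0.14), the cohesin gene psm3 (1.27 ± 0.11), tho2 (1.26 ± 0.11), the DNA repair gene rad50 (1.26 ± 0.11), gst2 (1.25 ± 0.13) and nup211 (1.23 ± 0.12). The deepest falls were urg2 (-1.73 ± 0.11) and urg1 (-1.41 ± 0.11), which respond to uracil, lsd90 (-1.63 ± 0.17), zym1 (-1.10 ± 0.10), scr1 (-1.03 ± 0.18), rsv2 (-1.0 ± 0.13), the invertase gene inv1 (-0.94 ± 0.11), gut2 (-0.91 ± 0.19), cdc16 (-0.84 ± 0.13), chs2 (-0.81 ± 0.12), pit1 (-0.80 ± 0.16) and wsc1 (-0.79 ± 0.16). The arrays also differed in a trend with gene length: the slope of an array's deviation from the mean of the 6 arrays was 0.070 and 0.11 per doubling of gene length in fkh2-S2A, -0.034 and -0.0095 in wild type and -0.074 and -0.061 in fkh2delta. With this trend removed the 2-fold split was 16 higher and 9 lower, against 36 and 6. The changes of single genes above are given without that removal, so the rises of long genes may include the trend.

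The mitotic genes did not move as a group in fkh2-S2A. Of 17 M-phase genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.635). The rises were myp2 (0.76 ± 0.12), bir1 (0.67 ± 0.14), imp2 (0.47 ± 0.11), mid1 (0.44 ± 0.11), pic1 (0.40 ± 0.12) and klp8 (0.38 ± 0.10), and klp5 (-0.45 ± 0.15) and cdc25 (-0.42 ± 0.14) fell with chs2. The klp5 and cdc25 calls were lost in 6 and 8 of 21 other settings, with changes down to -0.26 and -0.25 when fkh2-S2A replicate 1 was left out. The imp2, mid1, pic1 and klp8 calls ended when the length trend was removed and were lost in 3, 3, 4 and 5 settings in all. Of 18 middle meiotic genes 1 rose, mcp4 (0.94 ± 0.11), and 3 fell, with mes1 lowest (-0.70 ± 0.13), the same counts adjusted over the list alone (camera adjusted p = 0.340). Of 15 early meiotic genes 3 rose, led by rec10 (0.70 ± 0.12), also 3 adjusted over the list alone (camera adjusted p = 0.834). Of 10 mating genes 3 rose, ste4 (0.73 ± 0.12), mei2 (0.71 ± 0.12) and rgs1 (0.66 ± 0.11), and gpa1 fell (-0.53 ± 0.09), the same counts adjusted over the list alone (camera adjusted p = 0.635). Of 7 M-cell genes 3 fell (4 adjusted over the list alone), with mam3 at -0.57 ± 0.14, and of 3 P-cell genes map4 fell (-0.45 ± 0.10).

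Respiratory genes were slightly lower. Of 35 such genes 6 fell, with atp18 lowest (-0.74 ± 0.16), and 3 rose, among them atp12 (0.59 ± 0.14) and atp11 (0.42 ± 0.11), which encode assembly factors of the ATP synthase (11 and 4 adjusted over the list alone). The list's median was -0.25 (camera adjusted p = 0.00156, adjusted p = 0.495 with an estimated correlation). Camera also called the ribosomal protein list lower (adjusted p = 0.005, adjusted p = 0.858 with an estimated correlation), with a median of -0.04 and 0 of 111 genes past limma's test (0 adjusted over the list alone, 1 with an unadjusted p below 0.05, 8 with a mean-variance trend). When the trend with gene length was removed, the respiratory median was -0.21, near its former size, although its call ended (adjusted p = 0.0788). The ribosomal median then became 0.027 (adjusted p = 0.782). Stress genes tended the same way: 7 of 13 fell, such as hsp9 (-0.69 ± 0.09) and ctt1 (-0.65 ± 0.14), and 2 rose (7 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0596). Of 20 rRNA processing genes 6 rose, led by nop12 (1.04 ± 0.12; 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.117), of 17 MBF genes 5 rose, with psm3 and pol1 (1.16 ± 0.14) highest (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.635), and of 14 septation genes 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.635). Of 9 iron uptake genes str3 and fio1 (0.80 ± 0.20, lost in 3 of 20 other settings) rose, also 2 adjusted over the list alone (camera adjusted p = 0.635), and 0 of 9 histone genes passed in limma (0 adjusted over the list alone, 0 with an unadjusted p below 0.05, 0 with a mean-variance trend, camera adjusted p = 0.340). The forkhead gene sep1 fell (-0.54 ± 0.10), while fhl1 (0.22 ± 0.09) and mbx1 (-0.33 ± 0.15) did not pass, nor did mei4, which was not above background on either fkh2-S2A array. Of the Cdk8 module med13 (0.41 ± 0.12, adjusted p = 0.0268) passed, a call lost in 7 of 20 other settings with changes from 0.12 to 0.53, and srb8, srb10 and srb11 lay between -0.15 and 0.05. None of 7 auxotrophic marker genes passed in limma (0 with an unadjusted p below 0.05, 0 with a mean-variance trend), and of the flocculation genes mbx2 rose (0.58 ± 0.14, lost in 3 of 20 other settings).

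In all, 978 probe sets passed in fkh2-S2A, 689 higher and 289 lower. Without wild-type replicate 2 the count was 287, and the 2-fold count was 24 without that array and 85 without wild-type replicate 1. The split of the calls was 560 higher and 498 lower after median centring, 559 and 482 with trimmed-mean centring and 442 and 422 after quantile normalization, and it turned to 482 higher and 515 lower when the length trend was removed. With 2-fold, 25 probe sets passed when that trend was removed and 22 after quantile normalization.

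The direct comparison of fkh2-S2A with fkh2delta asked where the 2 mutants differ, with strain name and ura4 again differing too. M-phase genes were lower in fkh2-S2A than in fkh2delta: 13 of 17 (14 adjusted over the list alone), such as chs2 (-1.81 ± 0.12), ark1 (-1.25 ± 0.13), cdc15 (-1.07 ± 0.10) and klp6 (-1.06 ± 0.10). Of 18 middle meiotic genes 13 were lower and 1 higher, with meu14 at -5.75 ± 0.09 and mde2 at -2.88 ± 0.21, and of 15 early meiotic genes 8 were lower, with dmc1 at -3.35 ± 0.17 (both counts the same adjusted over the list alone). Camera called the 3 lists (adjusted p = 2.69e-05 for the M-phase and middle meiotic lists, 0.00309 for the early meiotic list), and none held with an estimated correlation (adjusted p = 0.534 with an estimated correlation for each). The early meiotic call was also lost after quantile normalization, where the list's median was -0.05 against -0.65. With 1 gene at its bound and 5, not above background in either group, set to 0, the early meiotic median was -0.12. The middle meiotic median was -1.24 and ran from -1.34 to -0.75 over 23 other settings.

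Of single genes, ura4 was 7.05 ± 0.21 and aes1 3.13 ± 0.09 higher in fkh2-S2A, and fkh2 was at least 5.43-fold higher. Next came klf1 (2.23 ± 0.10), wtf15 (2.13 ± 0.16), the biotin transporter gene vht1 (2.10 ± 0.12), alr2 (2.07 ± 0.22), put4 (2.03 ± 0.13), cat1 (1.98 ± 0.13), psf2 (1.86 ± 0.11), gmh1 (1.85 ± 0.19) and isp5 (at least 3.02-fold). Lower in fkh2-S2A were tlh2 (at least 50.1-fold), meu6 (-4.30 ± 0.14), mug20 (-3.94 ± 0.09), mug103 (at least 11.7-fold), spn6 (at least 6.55-fold), cid11 (-3.26 ± 0.10), meu25 (-3.25 ± 0.10), crp79 (at least 5.60-fold), zym1 (-3.09 ± 0.10) and mug133 (-3.04 ± 0.13). Of the remaining lists, MBF genes (3 higher, 6 lower of 17), septation (2 and 5 of 14), mating (3 and 5 of 10), stress (4 and 4 of 13), rRNA processing (6 and 5 of 20), respiration (10 and 11 of 35), iron uptake (2 and 4 of 9), histones (2 lower of 9) and ribosomal proteins (6 and 14 of 111, 68 called with a mean-variance trend) did not pass camera, with adjusted p from 0.134 to 0.847; adjusted over the list alone the counts were the same except for septation (2 and 6) and ribosomal proteins (0 and 1). For the MBF list the median (0.11) and camera's direction were up while the mean (-0.05) was below 0. The 3 flocculation genes were higher in fkh2-S2A, with cbf12 at 1.54 ± 0.12. In this comparison 1441 probe sets passed, 660 higher and 781 lower in fkh2-S2A, and 236 of them by at least 2-fold. The direction of this split depended on the scaling, with 777 higher and 728 lower after median centring and 808 and 718 after quantile normalization, but 727 and 772 with trimmed-mean centring.

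Across the 2936 probe sets, the changes of the 2 mutants against wild type had a Pearson correlation of 0.457 as labelled, and 0.0512 with the wild-type and fkh2-S2A labels exchanged; probe sets are not independent replicates. Both comparisons share the 2 wild-type arrays, and simulated mutants without any change gave 0.50. With a different wild-type array for each mutant the correlation was 0.404 or 0.429. The covariance was 0.123, against 0.0069 in the simulation. Of the probe sets that passed in both, 531 were higher in both mutants, against 278 for independent lists, and 168 were lower in both, against 68.2. These overlaps include the effect of the shared wild-type arrays. Opposite directions were found for 65 probe sets, against 279 for independent lists, a number that does not allow for the shared arrays.

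**Figure D3:**
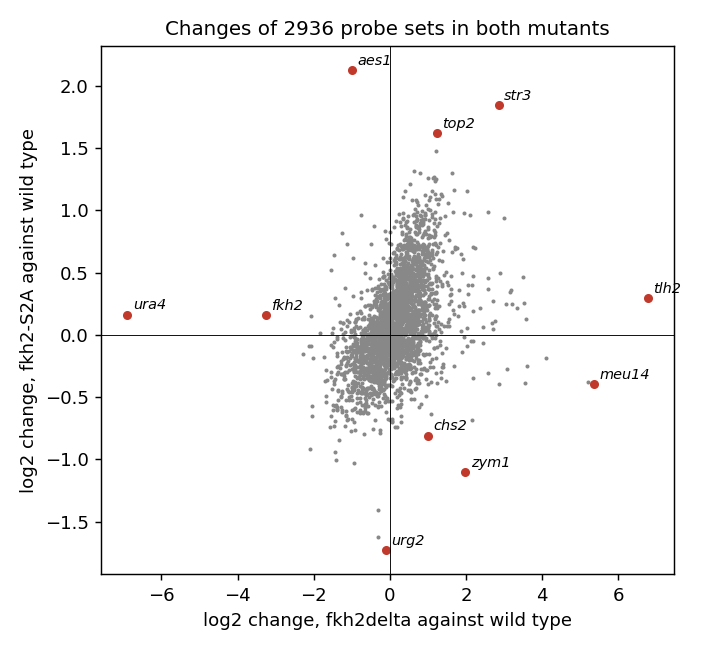
Log2 change of each of 2936 probe sets in fkh2delta (horizontal axis) and fkh2-S2A (vertical axis), each against wild type, n = 2 arrays per group; each grey point is a probe set and 10 named genes are red. The Pearson correlation across probe sets is 0.457 as labelled, with ura4 (-6.89) and tlh2 (6.77) far from the rest in fkh2delta and aes1 (2.13) highest in fkh2-S2A.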

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

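The test of exchanged labels was chosen after the values it uses had been seen; the test of the ura4 probe sets and their neighbours was set before its result, but which of its 2 values to put first, the probe-set count, was chosen afterwards.

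A control probe set for a reporter or marker sequence, which the sources used here name by an identifier alone, lay outside the main measurement and separated groups that share a strain name. Its mean was 12.6 (log2) in wild type and near that in fkh2delta, and the signal of fkh2-S2A minus that of wild type was -8.55; since it was below the background level on both fkh2-S2A arrays, this stands for at least 169-fold. In the same way ura4 was lost in fkh2delta. A complete deletion of ura4 in the fkh2delta strain was tested: 2 of 4 ura4 probe sets stayed above the background level on both fkh2delta arrays, which argues against the loss of every matching sequence, while the 5 measured genes on either side had a median absolute change of 0.368, with 6 of the 10 past the threshold and mug135, the nearest on 1 side, at 3.20; a partial deletion or cross-hybridisation may leave such a signal and was not tested. An exchange of the wild-type and fkh2-S2A labels stays open as a candidate explanation for the reporter: the covariance of the 2 mutants' changes above that of shared controls was 0.116 as labelled and 0.00539 with the labels exchanged, but an allele that acts unlike the deletion would also give a low value, so the 2 readings cannot be told apart here.

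Probe sets without a listed gene carried signal too. Above background, past the threshold and at least 2-fold changed were 253 of them in fkh2delta against wild type. The counts were 53 in fkh2-S2A against wild type and 154 between the mutants. None of the 2601 listed probe sets without an S. pombe gene met these criteria in any of the 3 comparisons (limma). At an unadjusted p below 0.05 that count was also 0. The background level was set from those same 2601 probe sets, so most of them could not count as above it. Their count of 0 is therefore no comparison for the unlisted probe sets.

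A further 65 probe sets changed in opposite directions in the 2 mutants against wild type; independent lists would give 279, but the 2 comparisons share the wild-type arrays, so that number is no measure of chance here. They include zym1 (1.98 in fkh2delta, -1.10 in fkh2-S2A), chs2 (1.00 and -0.81), meu14 (5.35 and -0.40), bgs2 (0.81 and -0.56) and aes1 (-1.01 and 2.13).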

How the results depend on the processing

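Settings added after seeing the data were the crossed block, the length trend, the unlisted probe sets and leaving out ura4; the cause of each difference was not tested unless said. The fall of fkh2 kept its direction and passed in all settings that kept its probe set (from -3.65 to -3.12); a filter that drops the dimmest 25% of the probe sets does not hold it. Counts in the order fkh2delta, fkh2-S2A, direct comparison were within 1.5 times of the reported ones except as follows. Testing all species gave 3352 and 2315 calls for fkh2delta and the direct comparison, 634, 94 and 391 with 2-fold, and 6 and 7 lists for fkh2delta and the direct comparison; adding unlisted probe sets gave 3216, 1657 and 2449 calls, 627, 93 and 384 with 2-fold, and 1 list for fkh2-S2A, since more probe sets were tested. That filter gave 198, 24 and 118 with 2-fold and 2 lists in the direct comparison. Fewer probe sets were tested, but the loss was also uneven. In fkh2delta the 2-fold rises went from 245 to 98 and the falls from 134 to 100. In the direct comparison the 2-fold lower calls went from 153 to 59 and the higher ones from 83 to 59. Many of the 2-fold rises in fkh2delta were thus in dim probe sets. For fkh2-S2A, quantile normalization gave 22 with 2-fold, removal of the length trend 25 with 2-fold and 0 lists, and an adjusted p of 0.01 gave 421 calls. For fkh2delta, median or trimmed-mean centring gave 5 lists, removal of the length trend 6 and fry 8. An estimated correlation gave 0 lists in each comparison. Leaving out 1 array gave 1407 to 1953, 287 to 921 and 980 to 1447 calls, 323 to 451, 24 to 85 and 205 to 281 with 2-fold, and 3 to 4, 1 to 3 and 4 to 5 lists; the lone array of a group was then assumed to vary like the others. The correlation of the 2 mutants was 0.377 without wild-type replicate 2 and 0.538 without wild-type replicate 1, and 0.542 as Spearman's rho. Reversals were seen under quantile normalization for mei4 (-0.49), med13 (-0.21) and srb10 (-0.58) in fkh2delta and for mei4 (0.0079), srb10 (0.50) and map2 (0.45) in the direct comparison; with the length trend removed for hhf3 in fkh2delta (-0.0046), map2 (0.27) and the ribosomal list (0.30) in the direct comparison and the ribosomal list in fkh2-S2A (0.027); and with fry for the stress list in fkh2delta (0.055). Of the named genes, 87 of 107, 58 of 108 and 79 of 108 kept their side of the threshold and direction in every setting. Same-numbered arrays deviated in opposite ways (r from -0.27 to -0.085), so these values give no sign that the numbers pair them. With 2 arrays per group the deviations in a group mirror each other, so these correlations cannot exclude a shared batch. With the replicate number as a block 1768, 836 and 1350 probe sets passed, and with the crossed block, chosen after seeing these correlations, 1890, 1014 and 1475.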

Other observations

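Of the tests below, the level-matched lists for meiotic genes and the length-matched lists were set before their results, and the others, with the form given here of the test of chromosome ends, after the values they use had been seen.

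Genes near chromosome ends were among the deepest falls in fkh2delta, which led to the hypothesis that genes nearest the ends are lower there. By gene order, the 25 measured genes nearest each end (150 genes) include 5 of the 12 deepest falls that prompted the test, such as put4, klf1 and cat1. Without these, the other 145 genes had a median change of 0.052, against 0.216 for random lists matched on wild-type level, and 0.46% of 10000 such lists were as low. Of the 150 genes 46 were higher and 52 lower, whereas of all 2936 probe sets 1186 were higher and 693 lower. By at least 2-fold 20 of the 150 were lower, or 13.3% against 4.15% of the other genes, a share that includes the 5 falls that prompted the test. Another 12 were higher by 2-fold, so the lower median is not a fall of every end gene. Among the end genes tlh2 and mug135, which lies next to ura4, rose most. The ends differed: medians over all 25 genes ran from -0.29 at the left end of chromosome II to 0.34 at its right end, so a lower level may hold for some ends and not for others. In fkh2-S2A 9 of the 150 genes fell and 43 rose, against 289 and 689 of all 2936 probe sets.

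The rise of middle meiotic genes in fkh2delta was weighed against 3 other explanations. Cells mating or in meiosis stay open: the 20 mating, M-cell and P-cell genes had a median change of 0.042, but 6 rose, among them mei2 and ste6, and 4 fell, and a high level in wild type could hide a small share of such cells in many of them. With each array centred on its median the list's median was 1.11 (camera adjusted p = 0.00108). The median of all probe sets was only 0.16 higher in fkh2delta, so centring could move the list's median little. An equal shift of all probe sets was therefore too small to give the list's 1.24. A shift that differs with signal level is not tested by centring. Among 10000 random lists matched on wild-type level 0.01% had a median as high, which argues against dim probe sets rising together as its whole cause. Such lists nevertheless had a median of 0.561, so probe sets at this level rose as a class and part of the list's 1.24 may be shared with them. An effect of losing fkh2 on these genes within growing cells and a share of cells in meiosis cannot be told apart here, and ura4 and other markers differ in the same strain.

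The lower respiratory and ribosomal lists in fkh2-S2A were weighed against the higher level of long genes there. For the ribosomal list the trend may be the whole cause: its median went from -0.04 to 0.027 when the trend was removed, and 100% of length-matched random lists were as low. Those random lists had a median of -0.11, so the ribosomal genes were less low than other genes of their length. For the respiratory list the median went from -0.25 (SD over genes 0.27) to -0.21 (0.23), with camera's adjusted p going from 0.00156 to 0.0788, and 0% of 10000 length-matched lists were as low. Removing the trend thus met neither outcome written for it (the call ended, but the median moved by less than 50%), and the verdict against length as the whole cause rests on the length-matched lists, a choice made after both values were seen. Less degraded RNA in fkh2-S2A would lower the 3′ minus 5′ difference of the control genes, which instead was 0.024 above wild type, within the 0.104 between arrays of a group. The slope with gene length had the other sign in fkh2delta, and what gives the arrays these trends was not tested further.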
